A study of Mus musculus with 2 samples.

How the data were processed

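DNase-seq was run on kidney tissue of 4-day-old male B6CASTF1/J mice in 2 samples that the labels number as biological replicates 1 and 2 of the same group. The labels do not say that the replicates came from separate animals, so their spread may be partly technical. Instrument models were listed for replicate 2 only. Per the labels the build was mm10, and the aligner, the peak caller, the footprint caller and the scaling of the heights are not given in the sources used here.

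For each sample the authors deposited 2 peak sets, a footprint set and a list of false discovery rates, each derived from the alignments of that sample alone, so replicates were called separately. The unit of the peak sets is a signal, the height of each peak, as deposited by the authors. Within a sample nearly all heights were whole multiples of a step (0.00485 in replicate 1 and 0.00488 in replicate 2; 100% and 99.9993% of heights within a tolerance of 0.05 of a step), as a count scaled by a factor would be. Read depth is not stated. The fewest steps in a peak were 10 and 9. The lists of false discovery rates hold p-value-like rates (q-values) per position, deposited by the authors up to 0.05 with no cut rate beside them. The stricter peak set, used throughout, had at least 1 position with a rate of at most 0.000996 in each peak that overlapped listed positions, and the more inclusive set, with 184689 and 210583 peaks, at least 1 with a rate of at most 0.05. Of the stricter peaks, 1106 and 1073 did not overlap the inclusive set of their own sample. The footprint files deposited by the authors hold the same p-value-like threshold, 0.01, for every footprint. The peak offset was 75 for every peak, so the middle of a peak was used as its position.

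Genes were the 21938 protein-coding genes of GENCODE release M21 on build mm10. A promoter was the 500 bp on each side of the annotated 5' end of a gene, and its height that of its tallest peak. Peaks not at a promoter were assigned to exon, intron or intergenic sequence, in that order. A distal peak lay more than 1000 bp from the annotated 5' end of every protein-coding gene and was given to the nearest such end within 100 kb. Promoters of other transcripts and of noncoding genes can therefore count as distal. Before the data were examined, 18 gene lists (7 of kidney cell types, 4 of other cells that a kidney sample could hold, 6 of other tissues and 1 of housekeeping genes), 28 consensus strings, the tests and the rule for the named genes were fixed. Height ratios between the replicates by string or by list, and distal counts by the mean, were not among the tests fixed then. Of 433 listed genes 432 matched the annotation.

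The share of open promoters of a list, and its median number of distal peaks, were set against 10000 random lists of the same size, matched on deciles of promoter CpG observed over expected, or of the width of the gene's nearest-gene territory, a permutation test over genes. The p-values were 2-sided and adjusted by Benjamini-Hochberg over the 18 lists with a threshold of 0.05. The smallest p that random lists can give is 0.0002. These tests describe the samples at hand and do not stand for other animals. Peaks overlapping by at least 1 bp counted as shared, and chance overlap came from 100 random circular shifts along each chromosome (20 for genomic classes and 10 for footprints). Consensus strings were searched on both strands in 200 bp windows at peak middles and in windows 1000 bp away without a peak, and compared by Fisher's exact test over windows, adjusted over 28 strings. Sequences were those of the reference build, and alleles of the CAST parent were not analysed here. For footprints the share of all footprint bases under matches, inside peaks or not, was compared with that of peak bases outside footprints. X was compared with autosomes by the ratio of median heights.

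The named genes were the 3 members of each kidney list (2 of the other lists) with the tallest promoter peak by the mean of the replicates, the 3 members of each kidney list with the most distal peaks, up to 3 members of each kidney list with no promoter peak in either replicate in alphabetical order, the 10 genes with the most distal peaks, the 10 tallest peaks, and the Hox genes as groups. Matches shown with their sequence, and single Hox genes, were chosen after the values were seen. Of the items that the rule or this choice takes, 2 are not reported here.

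Alternatives changed the promoter window (1000 or 100 bp), the 5' ends (all annotated transcripts), the peaks entering (those above the median height, the inclusive set, the same number in each replicate), the overlap (50% of both lengths), the reach (50 kb), the matching of random lists, the window length (100 bp), the background of the strings (the string written backwards), the footprint edges (3 bp wider), the summary for X, and left out each replicate. Heights could not be taken from the lists of false discovery rates, which hold no cut rate, and footprints could not be split by a score that is constant.

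The calculations were checked on simulated data. Of 200 random lists of 25 genes among 21938, 2.0% passed p under 0.05 for open promoters and 1.5% for distal peaks. With each member made open with a probability of 0.5, 74.5% passed p under 0.05. With 4 distal peaks added to each gene 99.5% passed, but with 2 added only 50.0%. These shares hold for p before adjustment and for lists drawn from all genes. They do not give the power of the list tests, whose calls needed an adjusted p under 0.05. A planted share of 70.1% shared peaks among 112640 was recovered as 70.7%, a planted single-peak SD of 0.5 as 0.501, and a planted X ratio of 0.5 over 649 promoter peaks as 0.499. A string planted in 80639 windows at a log2 ratio of 1.63 was recovered as 1.65, and one not planted gave 0.08. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.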

Results

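The series measured open chromatin in the kidney of male mice 4 days after birth with DNase-seq, which maps where the enzyme DNase I cuts DNA that is not packed into nucleosomes. The animals were B6CASTF1/J mice, hybrids of the laboratory strain C57BL/6J and the wild-derived strain CAST. Whether new nephrons were still forming in these kidneys at this age was not measured. The labels gave 1 group of 2 biological replicates, so no groups could be compared, and the error of each value is the spread between these replicates. The labels named 3 males and the same donor for both samples, and did not say whether the samples came from separate animals. Replicate 1 held 112640 peaks covering 21.2 Mb and replicate 2 held 133990 peaks covering 24.7 Mb of the mouse genome build mm10. The median peak was 180 bp long in both and had a deposited height of 1.11 in replicate 1 and 0.971 in replicate 2. Nearly all heights were whole multiples of a step of their sample, within a tolerance of 0.05 of a step, and a median peak held 228 steps in replicate 1 and 199 steps in replicate 2.

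Promoters of genes used by the cells of the kidney were open more often than those of comparable genes. A promoter was called open where a peak lay within 500 bp of the annotated 5' end of the gene. Of 180 genes in 7 lists of kidney cell types, 132 had an open promoter in both replicates. That share was 73.3%, against a median of 61.7% in random lists matched on promoter CpG content (permutation p = 0.0002, the smallest that the random lists can give). With only the peaks above each replicate's median height, the difference did not pass the threshold. The list of stroma, mesangium and vascular smooth muscle stood furthest above its random lists, with 24 of 25 promoters open against a random median of 56% (adjusted permutation p = 0.0018 over 18 lists). Its tallest promoter peaks were at Meis1, with a height of 9.16 ± 4.51 (SD, n = 2), and Meis2, with 8.86 ± 3.42, both homeobox factors of the renal stroma. A further tall peak was at Hic1, a transcriptional repressor of mesenchymal cells, with 6.67 ± 2.11.

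The nephron progenitor list had 23 of 24 promoters open, and the podocyte list 22 of 24. CpG-matched random lists were close to these shares, with medians of 87.5% and 83.3% (adjusted permutation p = 0.591 and 0.313). For the progenitor list these medians left little room for a call. With the inclusive peaks all of its promoters were open (100% against 91.7%), and the adjusted permutation p was still 0.214. The CpG-matched test therefore cannot tell whether progenitor promoters were open more often than comparable ones. Against random lists not matched on CpG, with medians of 62.5%, both lists passed the threshold (adjusted permutation p = 0.0018 and 0.0052). With the 5' ends of all annotated transcripts the podocyte list also passed (100% against 83.3%, adjusted permutation p = 0.0209). Among progenitor genes the tallest promoter peaks lay at Jag1, which encodes a Notch ligand, with 11.3 ± 1.39 (SD, n = 2), at Itga8, the integrin subunit of the cap mesenchyme, with 8.71 ± 3.99, and at Pax8, a paired-box factor of early nephrons, with 7.19 ± 2.10. Among genes of the list of podocytes, the epithelial cells of the glomerular filter, tall promoter peaks lay at Cd2ap, an adaptor protein of the slit diaphragm, with 18.2 ± 2.72, and at Rhpn1, with 11.1 ± 3.90. The endothelial list had 17 of 25 open promoters against a random median of 52% (adjusted permutation p = 0.313), led by the VEGF receptor gene Kdr with 4.47 ± 0.841, the TGF-beta co-receptor gene Eng with 4.15 ± 0.451 and the tight junction gene Cldn5 with 3.92 ± 1.94. With a 1000 bp window the endothelial share was 80% (adjusted permutation p = 0.0259), which passed the threshold, and with the 5' ends of all annotated transcripts it was 96% (adjusted p = 0.0012).

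Lists of the tubule segments did not stand apart from their random lists. The proximal tubule list had 13 of 28 open promoters (adjusted permutation p = 0.773), among them the endocytic receptor gene Lrp2 with a height of 4.20 ± 0.406 (SD, n = 2), the urea cycle gene Ass1 with 4.15 ± 0.341 and the water channel gene Aqp1 with 3.18 ± 0.818. The loop of Henle and distal tubule list had 15 of 27 (adjusted permutation p = 1), led by Pou3f3, a POU factor of the distal nephron, with 7.75 ± 3.85, by Irx3, with 6.30 ± 2.36, and by Wnk4, a kinase that sets sodium chloride transport, with 5.26 ± 0.673. The ureteric bud and collecting duct list had 18 of 27 (adjusted permutation p = 0.878), led by Hoxb7 with 8.76 ± 1.23, Tfcp2l1 with 7.57 ± 1.86 and Emx2, a homeobox gene needed for the ureteric bud, with 6.35 ± 0.00947. With the 5' ends of all annotated transcripts its share was 85.2% against a random median of 70.4% (adjusted permutation p = 0.0729).

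Some well known kidney genes had no peak at the 5' end that the annotation gives for the gene. In both replicates this held for Acsm2, Ggt1 and Hnf4a of the proximal tubule, Synpo of podocytes, Cldn10, Cldn16 and Esrrb of the loop and distal tubule, Aqp4, Ehf and Gata3 of the collecting duct, and Egfl7, Ehd3 and Erg of endothelium. For most of them a peak lay at the 5' end of another annotated transcript of the gene, at a mean height of 2.18 for Hnf4a, 3.83 for Synpo, 2.16 for Gata3, 4.22 for Ggt1, 4.01 for Egfl7 and 11.01 for Ehd3. Acsm2 and Cldn16 had none at any annotated transcript. With a 1000 bp window a peak was found at Ehd3 (11.01), Erg (1.72), Gata3 (1.64), Egfl7 (0.512) and Ehf (0.251). With only the peaks above each replicate's median height, the share of the pooled kidney genes fell to 57.2% and no longer differed from random lists (p = 0.145), while the stromal list still did (adjusted permutation p = 0.0024).

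Promoters of genes used in other tissues had a peak in both replicates less often than comparable promoters. Over 10 lists of other cells and tissues, 61 of 227 genes were open in both replicates, a share of 26.9% against a random median of 40.1% (permutation p = 0.0002, the smallest that the random lists can give), and 19 more had a peak in 1 replicate. Each of the germ cell, pancreas and photoreceptor lists fell below its random lists on its own. The germ cell list had 2 of 24 open promoters against a random median of 50% (adjusted permutation p = 0.0018), the pancreas list 1 of 22 against 31.8% (adjusted p = 0.0024), and the photoreceptor list 2 of 20 against 40% (adjusted p = 0.0108). With only the peaks above the median height the photoreceptor list no longer passed the threshold (adjusted permutation p = 0.185). These shares rested on few genes. Without replicate 1 they were 20.8% for germ cell (8.33% in both replicates), 9.09% for pancreas (4.55% in both) and 15% for photoreceptor (10% in both). Without replicate 2 they were 8.33%, 13.6% and 15%, and all stayed past the threshold, the weakest at an adjusted permutation p of 0.0459.

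The tallest promoter peak of the germ cell list was at Gdf9, an oocyte growth factor gene, with 22.8 ± 8.18 (SD, n = 2), and the 5' end of Uqcrq lay in the same window. Its next was the Tudor domain gene Tdrd1 with 0.703 ± 0.138. The 2 tallest of the pancreas list were Pdx1 with 0.559 ± 0.0940 and Cpb1 with 0.244 ± 0.345. Those of the photoreceptor list were the cone opsin gene Opn1sw with 8.67 ± 0.852 and Rom1 with 7.96 ± 0.926, whose window also held the 5' end of Eml3.

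The 3 other tissue lists did not pass the threshold, although each did under some alternative. The hepatocyte list had 3 of 25 open promoters (adjusted permutation p = 0.414), with Proc at 1.93 ± 0.331 (SD, n = 2) and Apoh at 1.62 ± 0.664, which was 13.1 with a 1000 bp window. The striated muscle list had 5 of 24 (adjusted permutation p = 0.313), with Mylpf at 14.6 ± 2.14, in a window shared with the 5' end of Tbc1d10b, and the calcium release channel gene Ryr1 at 2.57 ± 0.206. The neuron list had 15 of 24 (adjusted permutation p = 0.878), with the glutamate receptor gene Gria2 at 7.98 ± 3.82 and Nrgn at 6.71 ± 0.235. With the 5' ends of all annotated transcripts the striated muscle share was lower than in random lists (20.8% against 45.8%, adjusted permutation p = 0.0209), and that of hepatocytes was not (20% against 36%, adjusted p = 0.170). Both lists were lower than random lists not matched on CpG (adjusted permutation p = 0.000514 for each). With only the peaks above the median height the neuron share was 33.3% against 58.3% (adjusted permutation p = 0.0243).

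Cells that a dissected kidney could also hold gave no list that stood apart from random lists matched on CpG. The leukocyte list had 5 of 25 open promoters (adjusted permutation p = 0.839), with the myeloid factor gene Irf8 at a height of 6.92 ± 0.363 (SD, n = 2) and Cd74 at 1.30 ± 0.531. Against random lists not matched on CpG, with a median of 64%, its share of 20% was lower (adjusted permutation p = 0.000514). The erythroid list had 9 of 21 (adjusted permutation p = 1), with the red cell enzyme gene Bpgm at 21.9 in replicate 1 and 18.1 in replicate 2 and the transferrin receptor gene Tfrc at 15.4 ± 3.63. The adrenal gland list had 8 of 20 (adjusted permutation p = 0.773), with the vesicular amine transporter gene Slc18a1 at 22.6 ± 2.69 and the granin gene Chgb at 14.9 ± 5.96. The adipocyte list had 11 of 22 (adjusted permutation p = 0.839), with Gpd1 at 2.13 ± 0.143 and Cidea at 1.84 ± 0.687. Of the housekeeping genes 23 of 25 were open (adjusted permutation p = 0.839), with the chaperone gene Hspa8 at 36.7 ± 9.62 and the translation elongation factor gene Eef2 at 31.8 ± 0.279. Against random lists not matched on CpG their share of 92% was higher (median 64%, adjusted permutation p = 0.0054).

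**Figure D1:**
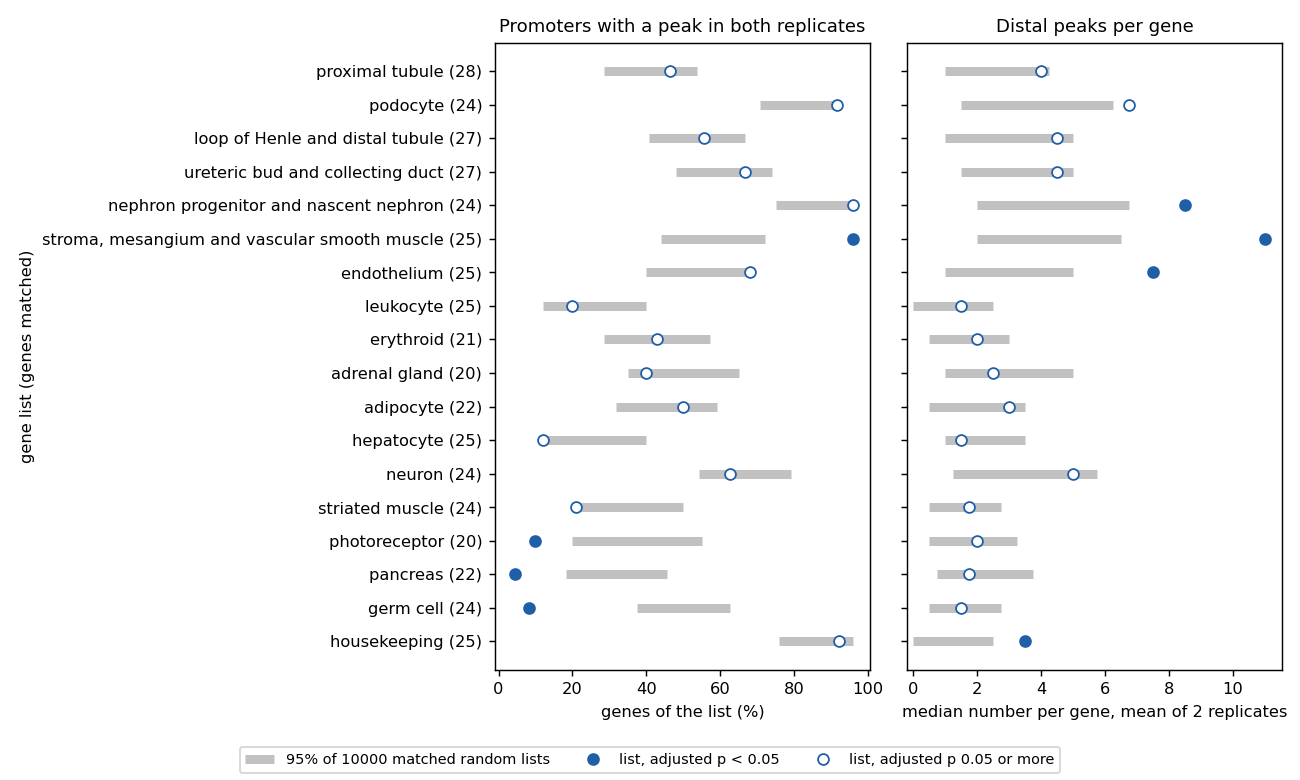
The left panel gives the percentage of genes of each of the 18 lists with a promoter peak in both replicates, and the right panel the median number of distal peaks per gene, as points (filled where adjusted p was under 0.05) over grey bars that span 95% of 10000 matched random lists. The stromal list lay above its bar in both panels, at 96% and 11 peaks, while the germ cell, pancreas and photoreceptor lists lay under theirs on the left.

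Distal peaks, more than 1000 bp from the annotated 5' end of any protein-coding gene, gathered near kidney genes. The median gene of the 7 kidney lists was the nearest gene, within 100 kb, to 6 such peaks (SD 0.707 over the replicates), against a median of 3 in random lists of genes with a territory of similar width (permutation p = 0.0002, the smallest that the random lists can give). The median over the 10 other lists was 2 and equalled that of their random lists (permutation p = 1). The stromal list had a median of 11 against 4 (adjusted permutation p = 0.0036), the endothelial list 7.5 against 2.5 (adjusted p = 0.0054) and the nephron progenitor list 8.5 against 4 (adjusted p = 0.0240). None of these list calls held with only the peaks above the median height, although the pooled excess did. The nephron progenitor call was also lost without replicate 1.

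The genes of these 3 lists with the most distal peaks included developmental regulators. Nr2f2, a nuclear receptor gene of stroma and veins, had 50 in replicate 1 and 56 in replicate 2, Hic1 33 and 22, and Meis2 22 and 25. Of the progenitor list, Pax2, a paired-box gene required for kidney formation, had 50 and 38, Uncx 24 and 19, and Jag1 11 and 31. Of the endothelial list, the VE-cadherin gene Cdh5 had 15 and 27, Ptprb 16 and 20, and Kdr 12 and 22. Ptprb had no peak at the 5' end annotated for the gene, but one at that of another annotated transcript, at a mean height of 1.88.

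The 4 other kidney lists did not pass the threshold on the median. The podocyte median was 6.75 against 3.5 (adjusted permutation p = 0.0994), with 24 and 26 distal peaks at Lmx1b, 25 and 24 at Tcf21, both transcription factor genes of podocytes, and 18 and 30 at Vegfa. The ureteric bud and collecting duct median was 4.5 against 3 (adjusted permutation p = 0.369), with 25 and 30 at Emx2, 28 and 20 at Wnt7b and 18 and 28 at Wnt11, a Wnt gene of the ureteric tip. The loop and distal tubule median was also 4.5 against 3 (adjusted permutation p = 0.369), with 19 and 24 at Irx3, 20 and 18 at Pou3f3 and 8 and 17 at the potassium channel gene Kcnj1. The proximal tubule median was 4 against 2.5 (adjusted permutation p = 0.369), with 17 and 24 at the urate transporter gene Slc22a12, 15 and 18 at Ass1 and 13 and 11 at Pck1.

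Counted by the mean instead of the median, which was not planned, the podocyte list (9.46 against 5.15, adjusted permutation p = 0.00432) also had more distal peaks than its random lists. So had the collecting duct list (7.57 against 4.37, adjusted permutation p = 0.0126) and the housekeeping list (5.22 against 2.44, adjusted permutation p = 0.00432). By the median, housekeeping genes had 3.5 against 1 (adjusted permutation p = 0.0243), a call that was lost under each alternative run on the median, including without replicate 1 (median 3, adjusted p = 0.211) and without replicate 2 (median 2, adjusted p = 0.998). With only the peaks above the median height no kidney list passed (adjusted permutation p = 0.118 for each of the 3), although the pooled kidney genes did (median 2.5, p = 0.0002). Without replicate 1 the nephron progenitor list did not pass (adjusted permutation p = 0.170).

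Over the whole genome Sik1, a kinase gene induced by cAMP, and Zfp36l2, which encodes an RNA-binding protein, had the most distal peaks by the mean of the replicates. Sik1 had 53 in replicate 1 and 85 in replicate 2, and Zfp36l2 had 69 and 67, so their order differed between the replicates. Nr2f2 followed, then the corepressor gene Bcor with 48 and 52, Zmiz1 with 52 and 44, Pax2, Cxxc5 with 42 and 45, Cstad with 33 and 50, the corepressor gene Tle3 with 37 and 44, and Bahcc1 with 31 and 48. The median protein-coding gene had 2, and 6115 of 21938 had none.

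Promoters took 15.7% ± 2.10 (SD, n = 2) of the peaks, 16.1 times the share of peaks shifted at random along their chromosomes (0.974%). Exons outside promoters held 10.7% ± 1.28, introns 34.9% ± 1.76 and intergenic sequence 38.7% ± 1.62, against shifted shares of 4.87%, 34.8% and 59.4%. The share at promoters depended on what counted as one, and was 25.5% among the peaks above the median height and 9.82% with a window of 100 bp. Promoter peaks were taller, with a median height of 4.15 ± 0.0204 against 0.902 ± 0.0478 at distal peaks. Of 21938 protein-coding genes 13718 had an open promoter in both replicates (62.5%), from 2.78% in the decile of promoters poorest in CpG to 98.7% in the richest.

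The tallest peak by mean height was X:169998261-169998420 (replicate 1 position), in an intron 11318 bp from the 5' end of Gm21887, with 58.8 in replicate 1 and 124 in replicate 2. The 36 bp at its middle occurred 8 times in the genome, so its reads can match several places. The next were promoter peaks of the dynein light chain gene Dynlt1b (17:6430021-6430180) with 73.1 ± 2.79 (SD, n = 2), Hjurp, a chaperone of centromeric histone, with 65.6 ± 7.38, Bahcc1 with 57.9 ± 9.25, Mplkip with 57.1 ± 2.12, Ankhd1 with 55.7 ± 10.4 and Dnpep with 53.2 ± 13.7. An intergenic peak at 8:20424741-20424920, nearest to Gm15319, had 57.6 in replicate 1 and 39.1 in replicate 2, followed by promoter peaks of Snrnp70 with 46.8 ± 8.43 and Srl with 46.4 ± 1.44.

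The replicates shared most of their peaks, and promoters more than distal sites. Of the peaks of replicate 1, 83.7% overlapped a peak of replicate 2 by at least 1 bp, and of those of replicate 2, 70.2% overlapped one of replicate 1, a mean of 76.9% ± 9.55 (SD, n = 2). Both shares count the same overlaps (94276 and 94055 peaks), so this SD mostly reflects the unequal peak totals and is not an error of the sharing. Over 100 random shifts the shares were at most 2.12% and 1.76%. At promoters 90.9% and 91.2% were shared, and at distal sites 82.4% and 66.0%. Peaks that were not shared were low, with median heights of 0.543 and 0.561 against 1.35 and 1.38 for shared peaks, and 55.2% and 56.7% of them overlapped a peak in the more inclusive set of the other replicate.

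Over 92979 pairs of shared peaks the log2 heights had a Pearson r of 0.864 and a Spearman rho of 0.828, across peaks, which are not independent replicates. The SD of a single peak's log2 height was 0.56, against 0.10 from counting alone. At promoters r was 0.956 with an SD of 0.37, and 6.24% of the pairs differed more than 2-fold. At distal sites r was 0.776 with an SD of 0.61, and 24.0% of the pairs differed more than 2-fold. Over pairs above the median height rho was 0.671.

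Distal peaks that hold a match to the consensus of CTCF, the zinc finger protein of insulators and chromatin loops, were taller in replicate 1. Over 5204 pairs the median log2 ratio of replicate 1 to replicate 2 was 1.16, a 2.23-fold difference, and 91.6% were taller in replicate 1. Pairs with a match to REST, a repressor of neuronal genes, differed in the same direction, with a median of 1.49 over 325 pairs and 97.2% taller in replicate 1. Distal pairs without a CTCF match had a median of -0.17. In the other direction, pairs with a match to HNF1, the homeodomain factor of tubule epithelium, had a median of -0.87 over 34 pairs, HNF4 -0.40 over 329 and TEAD -0.42 over 2334. Strings of other factors were as low as HNF4, with MEF2 at -0.40, E-box at -0.39 and PU.1 at -0.39. These ratios by string, and the tests by list that follow, were not planned. Distal peaks near endothelial genes were lower in replicate 1, with a median log2 ratio of -0.37 against -0.04 in random lists (adjusted permutation p = 0.0432). No other of the 18 lists differed. The proximal tubule list had -0.35 (adjusted permutation p = 0.0504). Pooled over the 7 kidney lists the median was -0.15 against -0.04 (permutation p = 0.0162), and over the 10 other lists 0.17 against 0.06 (permutation p = 0.0850).

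**Figure D2:**
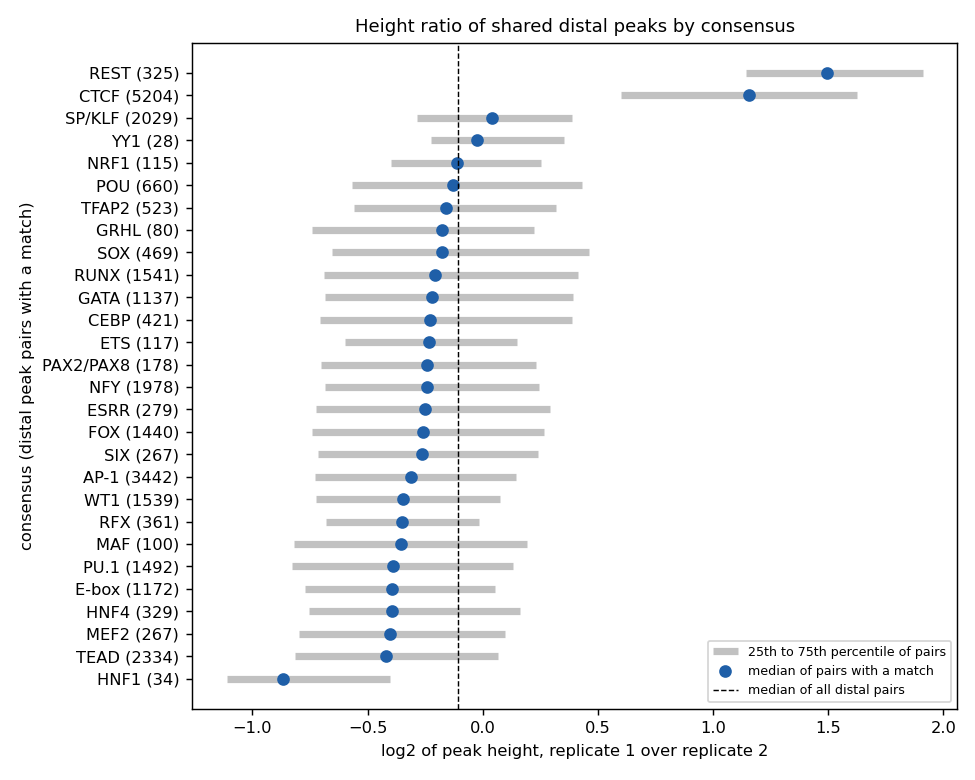
Each point is the median log2 ratio of peak height, replicate 1 over replicate 2, of the shared distal pairs that match 1 of 28 consensus strings, the grey bars span the 25th to the 75th percentile of the pairs, and the dashed line marks the median of all distal pairs (-0.11). REST (1.49) and CTCF (1.16) lay far to the right of the others, and HNF1 (-0.87) furthest to the left.

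Matches to CTCF and REST were the most enriched of 28 consensus strings in distal peaks. Those to CTCF lay in 5.81% ± 1.32 (SD, n = 2) of the 200 bp windows at peak middles against 0.0775% of windows 1000 bp away, a log2 ratio of 6.21 ± 0.43. REST followed with 5.89 ± 0.77, then SP/KLF, the factors that bind GC boxes, with 3.33 ± 0.22 (3.07 for the string written backwards). Next came NRF1 with 2.49 ± 0.24 and YY1 with 2.09 ± 0.19. Distal peaks can include promoters of other transcripts and of noncoding genes, so these ratios do not describe enhancers alone. In all, 21 strings were more frequent in peaks than in flanks in both replicates, 3 were less frequent and 4 did not pass Fisher's exact test over windows in both. The consensus written backwards served as a control of equal base composition, though reversal can change the number of CpG pairs. Of the 21, 18 exceeded it, SP/KLF by only 0.25 and E-box by 0.19. TFAP2 (1.07 against 1.45) and PAX2/PAX8 (1.36 against 1.39) did not, and YY1 had no backwards value.

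Strings of factors known from kidney epithelium were among those enriched. HNF1 had 1.61 ± 0.65 (SD, n = 2) against -1.17 backwards (Fisher's exact test, largest adjusted p of the replicates 0.00189), and HNF4, a nuclear receptor of the proximal tubule, had 0.84 ± 0.27 against -0.51 (4.26e-10). The string TCAGGTTTC of factors such as Six2 of nephron progenitors had 0.65 ± 0.13 against 0.39 backwards. The calls of HNF1 and of this string were lost with 100 bp windows (Fisher's exact test, adjusted p = 0.195 and 0.107). GRHL, of the collecting duct epithelium, had 1.35 ± 0.06, WT1, of podocytes and progenitors, 1.30 ± 0.15, TEAD, the partner of YAP, 0.81 ± 0.25 and AP-1 0.55 ± 0.18. ETS had 1.51 ± 0.07, RFX 1.48 ± 0.15, MAF 1.34 ± 0.27, E-box 1.25 ± 0.18 (1.06 backwards), PU.1 0.72 ± 0.21, NFY 0.37 ± 0.07 and CEBP 0.30 ± 0.10, whose call was lost with the inclusive peaks.

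GATA with -0.49 ± 0.12 (SD, n = 2), ESRR with -0.44 ± 0.21 and POU with -0.28 ± 0.04 were less frequent in peaks than in flanks, and the call of ESRR was lost with 100 bp windows (Fisher's exact test, adjusted p = 0.0774). RUNX, FOX, SOX and MEF2 were not called. Against their own backwards strings in the same windows, GATA (0.25), ESRR (0.74) and POU (4.33) were more frequent, and ETS (-1.53), GRHL (-2.01) and PAX2/PAX8 (-0.41) less frequent. In replicate 1 flanks the order was the same for POU (1774 windows against 209 backwards), ETS (82 against 596) and GRHL (71 against 511). It was also the same for ESRR (916 against 519) and PAX2/PAX8 (153 against 191), but not for GATA (3790 against 4327). Such a comparison sets a string against a different one, so it does not say how peaks differ from flanks.

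Sequences behind some of these strings in mm10 (plus strand) were chosen after the values were seen. Each comes from the tallest shared distal peak, by mean height, whose match overlapped a footprint in both replicates. For CTCF it was the intergenic peak 8:20424741-20424920, with the match GCCCTCTGGTGG at 8:20424870-20424881 and heights of 57.6 and 39.1. For REST it was 14:63681601-63681800 in an intron of Xkr6, with AGCACCACGGACAG at 14:63681622-63681635 and heights of 45.1 and 21.3. For HNF4 it was 12:80230121-80230300 in an intron of Actn1, with CAAAGTCCA at 12:80230266-80230274 and heights of 7.63 and 16.3. For TEAD it was 11:74832201-74832400 in an intron of Mnt, with TGGAATGT at 11:74832226-74832233 and heights of 28.9 and 35.5.

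**Figure D3:**
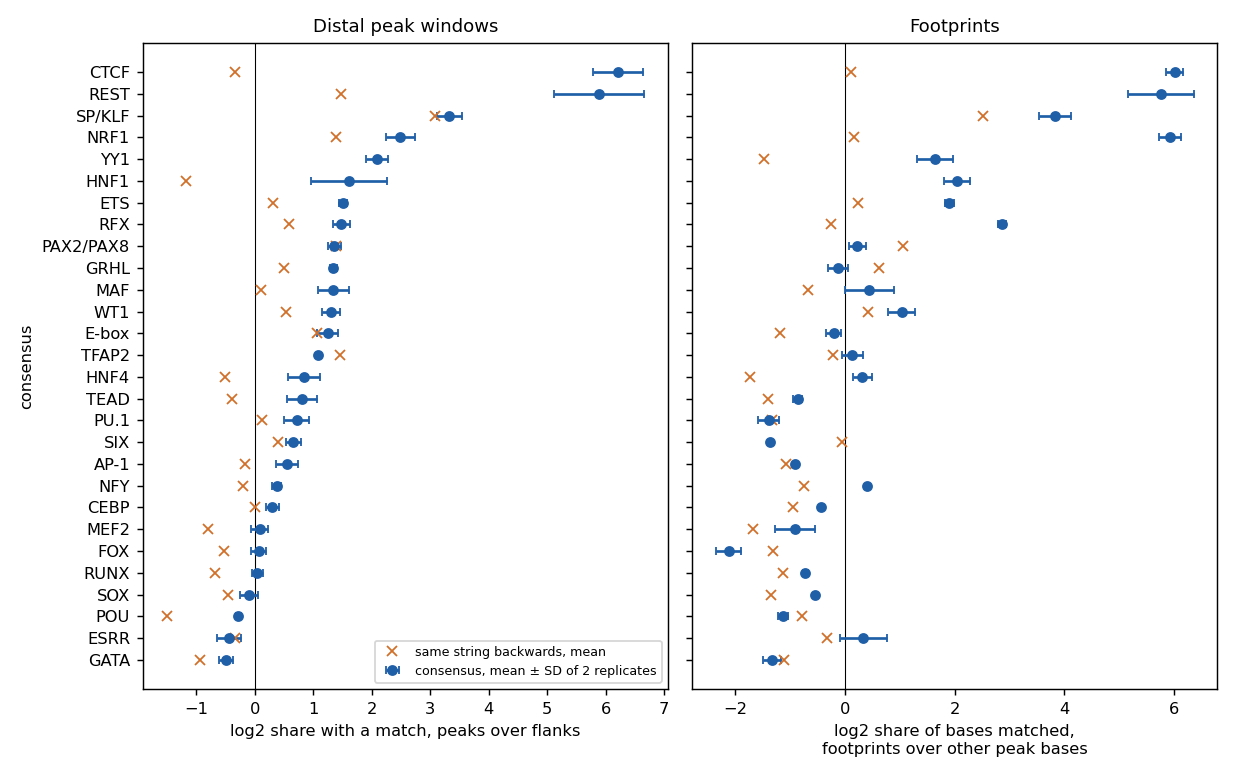
Blue points give the mean log2 ratio of 28 consensus strings, with the SD of the 2 replicates as bars. The left panel sets distal peak windows over flanking windows, and the right panel all footprint bases over peak bases outside footprints. Orange crosses give the same for the string written backwards. CTCF (6.21 and 6.01) and REST (5.89 and 5.76) lay far to the right in both panels, and FOX (-2.12) furthest to the left in footprints.

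Footprints are short stretches within open chromatin that are cut less than their surroundings, as a bound protein leaves them. The authors' files listed 491396 in replicate 1 and 566253 in replicate 2, with a median length of 11 bp in both, and 61.8% ± 1.18 (SD, n = 2) of them lay inside peaks. Of the peaks 91.1% and 92.5% held at least 1. Fewer footprints than peaks were shared between the replicates, at 55.9% ± 4.89, against 0.605% and 0.534% after random shifts, and 40.2% were shared where the overlap had to cover 50% of both. As for peaks, the SD of the shared percentage mostly reflects the unequal totals of the replicates.

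Matches to CTCF (log2 ratio 6.01 ± 0.16, SD, n = 2), NRF1 (5.93 ± 0.20) and REST (5.76 ± 0.60) were the most concentrated in footprints relative to peak bases outside footprints. Footprint bases outside peaks were counted too, so the ratios, high or low, also carry differences between sequence inside and outside peaks. SP/KLF had 3.84 ± 0.29, RFX 2.86 ± 0.07, HNF1 2.05 ± 0.24, ETS 1.90 ± 0.08, YY1 1.65 ± 0.33 and WT1 1.04 ± 0.25. In both replicates 14 strings were more frequent in footprints and 12 less frequent, the latter including FOX (-2.12 ± 0.23), PU.1 (-1.39 ± 0.20), GATA (-1.32 ± 0.16), POU (-1.12 ± 0.09), AP-1 (-0.91 ± 0.02) and TEAD (-0.86 ± 0.08). GRHL and TFAP2 went opposite ways in the replicates. Against their backwards strings inside footprints, 23 strings were more frequent and 4 less frequent. AP-1 (0.92), TEAD (2.31), POU (4.02) and PU.1 (0.64) were among the more frequent. Such values set a string against a different one and do not say how footprints differ from other bases. Footprint files gave no test, and the ratios carry only the spread between replicates.

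Most of the 39 Hox genes, the homeobox genes that mark position along the body axis, had an open promoter. In both replicates 34 were open, among them 21 of 23 of paralog groups 1 to 8 and 10 of 10 of groups 9 to 11, but 3 of 6 of groups 12 and 13. The median of the tallest promoter peak was 4.51 ± 1.31 (SD, n = 2) in groups 1 to 8 and 4.19 ± 0.231 in groups 9 to 11, and 0.810 ± 0.569 in groups 12 and 13. Hoxc10 had the tallest peak of all, with 20.1 ± 2.93, followed by Hoxa7 with 13.2 ± 3.69, Hoxa4 with 12.2 ± 0.169 and Hoxa10 with 12.2 ± 1.60. Hoxc12 had no peak in either replicate, and Hoxa13 (1.27), Hoxd13 (1.22) and Hoxb3 (0.509) had one in replicate 1 only, while Hoxb8 had one in replicate 2 only (2.37). The Hoxa cluster had a median of 5.12 ± 0.778 and Hoxc one of 2.60 ± 0.716.

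**Figure D4:**
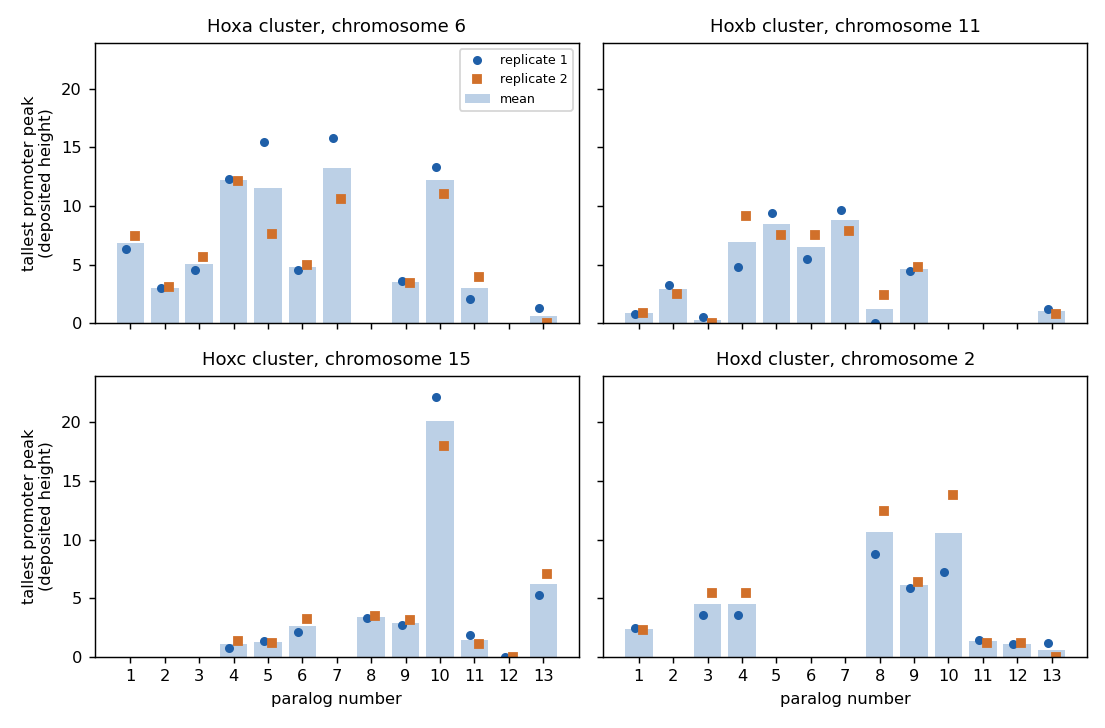
Each panel is 1 of the 4 Hox clusters, with the paralog number on the horizontal axis and the deposited height of the tallest promoter peak on the vertical axis, where bars are means and points the 2 replicates. Hoxc10 had the highest mean (20.1), while genes of paralog groups 12 and 13 other than Hoxc13 (6.19) had means of at most 1.11.

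Peaks on the X chromosome, of which male mice have a single copy, were lower than peaks on the autosomes. At promoters the median height on X was 0.485 ± 0.0662 (SD, n = 2) times that on autosomes, from 649 peaks in replicate 1 and 609 in replicate 2. The lowest single autosome, 13, was at 0.774 and 0.820. At distal peaks the ratio was 0.604 ± 0.0240, from 1961 and 2320 peaks, where the lowest single autosome was at 0.882 and 0.883. X therefore lay outside the range of the autosomes in both replicates and both kinds of peak.

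**Figure D5:**
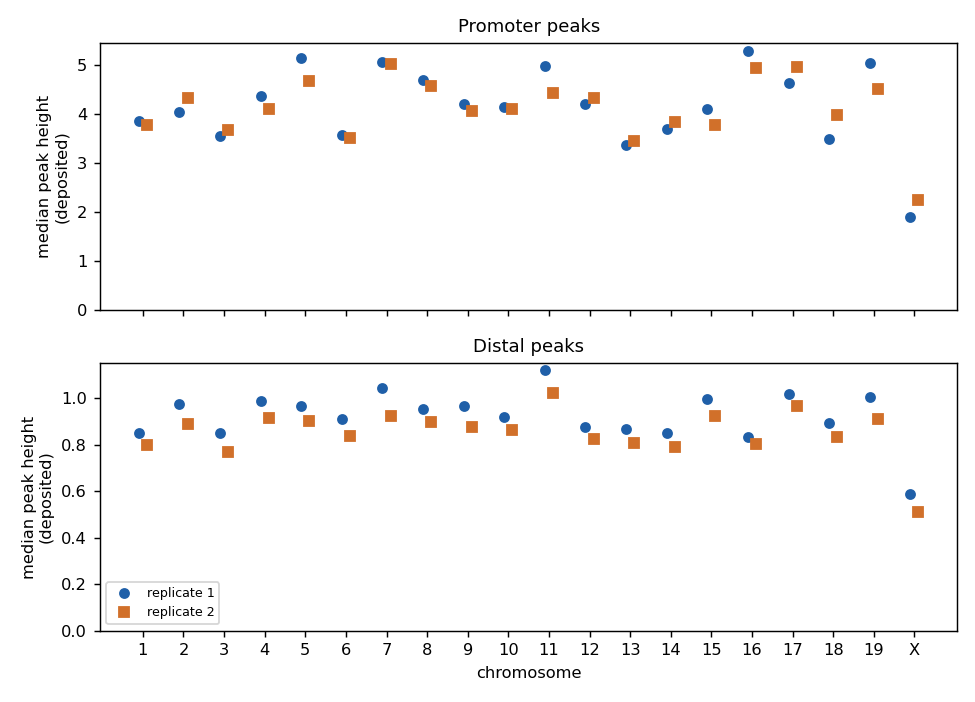
Points give the median deposited height of promoter peaks (top) and distal peaks (bottom) on each autosome and on X in the 2 replicates. X lay below each autosome in both panels, at 1.90 and 2.24 for promoter peaks and 0.587 and 0.512 for distal peaks.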

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

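Settings using the inclusive peak set, and pairs without CTCF or REST matches or at promoters only, were chosen after seeing the data; the others were planned. Of 117 recomputed values of 22 main results, 96 stayed within their spread, on their side of the threshold or, for counts, within 1.5 times the main count, 20 moved, 1 lost its call and 0 reversed, and for each of those that did not stay the cause was not tested. The height correlation (rho 0.828) was 0.671 above the median height, 0.839 without CTCF or REST matches and 0.955 at promoters. The promoter share (15.7%) was 20.1% at 1000 bp, 9.82% at 100 bp, 22.8% with all transcripts, 25.5% above the median height and 10.8% in the inclusive set. With peaks above the median height, the open share of kidney genes was 57.2% (permutation p = 0.145), and 0 kidney lists, in place of 3, had more distal peaks. Kidney lists with more open promoters numbered 2 at 1000 bp, 3 with all transcripts and 3 without CpG matching, in place of 1, and other lists with fewer numbered 4 with all transcripts and 6 without CpG matching, in place of 3. Within that limit for counts, kidney lists with more distal peaks numbered 2 without replicate 1 and 4 with inclusive peaks, and strings more frequent in peaks than in their background (21) numbered from 19 with 100 bp windows to 24 without replicate 1 or with backwards strings as background. Without matching on territory 6 kidney lists and 1 of the other lists had more distal peaks. Of footprints 80.3% lay in inclusive peaks, and 40.2% were shared at 50% of both lengths. X over autosomes at distal peaks was 0.692 by the mean. With backwards strings as background, windows gave ETS -1.53, GRHL -2.01, PAX2/PAX8 -0.41, GATA 0.25, POU 4.33 and ESRR 0.74, and footprints gave 23 strings higher and 4 lower, with AP-1 0.92, PAX2/PAX8 -1.35, TEAD 2.31, RUNX 1.48, POU 4.02, SOX 1.80, MEF2 2.31, E-box 5.26, PU.1 0.64 and CEBP 2.12. Of 234 values for single lists 207 kept their status, called or not called, while 11 lost and 16 gained a call. Of 277 values for single strings 219 stayed, 30 moved, 4 lost and 8 gained a call, and 16 reversed. Values against backwards strings compare different strings, so a reversal there does not say how peaks or footprints differ from their surroundings. Of 385 promoter heights of named genes 357 stayed and 28 moved. With 2 replicates, the values with one left out carry no spread. Such a value always lies within the SD of the 2 replicates, so where the SD was the measure it counted as stayed in advance. This held for promoter heights of named genes, strings in footprints, the promoter share, footprints inside peaks and X over autosomes. Those values are no evidence of stability. Heights from per-position cut rates, for the correlation and X, and stricter footprints by score were not run, since the files hold no such measure. No paired analysis was possible because there was 1 group. At 9 to 10 steps in the lowest peaks, sites below that height were not called, so an unlisted site is not shown to be closed.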

Other observations

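Gene families that the fixed lists did not cover were chosen after the data were seen, 20 in all, and were set against the same matched random lists. Olfactory receptor genes, which act in sensory neurons of the nose, rarely had a promoter peak in both replicates, with 9 of 1135 open (0.793%, against a random median of 7.67%, adjusted permutation p = 0.0008), as did the vomeronasal receptors with 1 of 329 (adjusted p = 0.0008). Keratin genes of surface epithelia were open in 8 of 53 (15.1% against 41.5%, adjusted permutation p = 0.0008). Collagen genes, which make the fibres and basement membranes between cells, went the other way, with 35 of 45 open (77.8% against 62.2%, adjusted permutation p = 0.0129) and a mean of 8.27 distal peaks per gene against 5.19 (adjusted p = 0.008), led by Col5a1 with 25, Col18a1 with 24 and Col13a1 with 23. Zinc finger genes named Zfp were also open more often, in 327 of 394 (83.0% against 75.6%, adjusted permutation p = 0.0008).

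The Wnt ligand and forkhead factor genes had fewer open promoters than matched genes and yet more distal peaks. The Wnt ligand genes had 11 of 19 open promoters (57.9% against 84.2%, adjusted permutation p = 0.0095) but a mean of 8.66 distal peaks against 4.29 (adjusted p = 0.01), led by Wnt7b with 24, Wnt11 with 23 and Wnt4, which drives nephron formation, with 18. The forkhead factor genes had 29 of 44 (65.9% against 84.1%, adjusted permutation p = 0.0008) and 6.77 against 4.39 (adjusted p = 0.0192), led by Foxl1 with 26.5 and Foxo1 with 20.5. Pax genes had 3 of 9 open promoters (adjusted permutation p = 0.00467) and T-box genes 6 of 16 (adjusted p = 0.00743), with distal counts that did not pass the threshold (adjusted p = 0.081 and 0.145). Solute carrier genes, which include the transporters of the tubules, had slightly more distal peaks than matched genes, 4.31 against 3.69 (adjusted permutation p = 0.0193). Ribosomal protein genes were open in 75 of 82, the same share as their random lists. The remaining families, among them Sox, claudin and aquaporin genes, passed in neither measure.

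For 3 patterns explanations were tested; the tests of the cell mix and of adrenal cells were chosen only after the result was seen. Distal peaks with a CTCF or REST match were taller in replicate 1. A scaling that changes with height was argued against, since CTCF pairs exceeded other distal pairs of the same height by 1.22 (log2; 95% bootstrap interval 1.20 to 1.24), and so was GC content, with an excess of 1.32 (1.29 to 1.35) at matched GC. A different mix of cell types stays open: CTCF pairs exceeded the promoters of housekeeping genes by 1.32 (1.12 to 1.59, 30 pairs), which excludes it only if CTCF sites are equally open in all cells of the kidney, and distal pairs near kidney genes (-0.15, permutation p = 0.0162), near endothelial genes (-0.37) and with an HNF1 match (-0.87) were lower in replicate 1. A difference in library preparation or sequencing cannot be told apart from the replicates, since each replicate is a single library and instruments were listed for replicate 2 only, and the design, with a single group, gives no biological contrast to test.

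Peaks on X were lower than on autosomes. Lower CpG content of X promoters was argued against as the whole cause, since at matched CpG the ratio was 0.594 ± 0.0725 (SD, n = 2), against 0.467 ± 0.0777 unmatched for the same 445 genes. The matched value is a median of ratios per gene and the unmatched value a ratio of medians. The gap between them is therefore not a measure of the part due to CpG. If the single X of males halved the cut DNA, sites shared by most cells would lie near 0.5, and a range of 0.4 to 0.6 in both replicates was set in advance. CTCF-match distal peaks had a ratio of 0.3999 ± 0.0249, with 0.382 in replicate 1 (95% bootstrap interval 0.290 to 0.459, 149 peaks) and 0.418 in replicate 2 (0.370 to 0.488, 127 peaks), while single autosomes ranged from 0.819 to 1.22 in replicate 1. In replicate 2 single autosomes ranged from 0.860 to 1.18. Both intervals lay below 0.5, but they resample only the peaks on X and leave out this spread between chromosomes. They therefore cannot tell whether these sites on X were lower than a halving alone would make them. The single X copy stays open as a candidate explanation for part of the difference. Replicate 1 fell under the range by less than its interval, and no females were measured.

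Promoters of some genes of the adrenal gland and neuron lists had tall peaks in kidney. Adrenal cells in the samples stay open, since 40% of the adrenal list was open against a random median of 50% (95% of lists 35% to 65%), with Slc18a1, Chgb, Fdx1 and Star open and no peak in either replicate at Cyp11a1, Cyp11b1, Cyp21a1 and Th. REST sites remain a candidate explanation for part of the pattern: 4 of the 23 open promoters of these lists held a REST match (Gad2, Grin1, Gria2 and Chga), 82.1 times the share of other open promoters (29 of 13695, Fisher's exact test, p = 2.38e-07). REST is a repressor of neuronal genes, so that excess can come from the choice of genes and does not address height. The median height of the 4 was 5.87 ± 3.06 (SD, n = 2) against 1.59 ± 0.543 for the 19 without a match. Gria2 and Chga lay above the median promoter peak (4.15), but Gad2 (2.14) and Grin1 (3.76) lay below it. Scg2 (12.2), without a match, was taller than each of the 4. Slc18a1 and Chgb, the tallest of the adrenal list, held no match within 500 bp of the 5' end. Their peaks lay mostly outside that window, so the search cannot tell whether REST sites lie under them.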
